A study of Homo sapiens with 36 samples.

How the data were processed

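RNA sequencing libraries of the SCC25 line were grouped by the labels into 11 PBS and 11 cetuximab libraries (weeks 1 to 11), 3 parental libraries and 11 resistant clones. Per the labels' protocols, polyadenylated RNA was sequenced, reads were aligned to hg19 with MapSplice and genes were quantified with RSEM. The submitters' processing notes also name Picard 1.93 and SAMtools 0.1.19. The authors deposited 1 table of normalised signal values, in which each library's estimated gene counts are scaled so that the upper quartile of its genes above 0 is near 1000. The lowest and highest upper quartiles were 997.2 and 1000.0. The design text names a log transformation, but the deposited signal values are linear and were used as such. It also gives fewer samples than were analysed here.

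Gene symbols and Entrez identifiers are those of the table. Of its 20531 identifiers 20372 matched a current symbol and 19899 genes were placed on GRCh37, the build also called hg19. Depth was recovered from the steps between low values: 88.1% to 89.4% of the values below 1000 counts came out whole within 0.05, too few to treat them as whole reads, so no count test was run. A value of 1 count was worth 0.339 to 0.876 normalised units, and the 10 highest genes took 3.79% to 5.48% of each library. The estimated totals bear on precision: totals ran from 18400000 to 48800000 counts per library, and low-value genes are measured least precisely. No interval for single values is given, since the values are estimates.

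Values were transformed to log2(value + 1). Genes were tested if their mean over the libraries of a fit reached the median upper quartile minus 6 on the log2 scale, a floor of 3.97 (14.6 normalised units). Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), two-sided, with Benjamini-Hochberg adjustment at 0.05. The comparisons were cetuximab against PBS over all weeks, in weeks 1 to 4 and in weeks 8 to 11, the difference of the last 2, the slope per week in each arm and their difference, and clones against parental cells. The early and late comparisons come from 1 fit of all 22 time-course libraries with 6 cells of arm and period. Standard errors of single genes are those of limma's moderated fit, and those of medians over genes come from resampling the genes.

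Named genes followed a rule: per comparison, the 8 largest rises and falls past the threshold with a mean at or above the median upper quartile minus 4 in the higher group and the same direction in at least 10 of 11 weeks, 4 of 4 weeks or 11 of 11 clones. To these were added a panel of receptors, ligands and markers and up to 3 members of each called gene list, and for changes over time the 5 largest in each direction. The rule, the 30 gene lists, the samples of each test and the alternatives other than those said below to be added later were set before the data were examined. DCN, PDPN, LUM and COL1A1 come from the list of fibroblast markers and were named beside the list. ETV1 is given early and late for the difference that names it.

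Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 27 lists with 3 or more tested genes. An estimated correlation was tried for each list and comparison, and 1 of 75 calls held with it. No called list result had a median of the other sign under median centring or quantile normalisation (0 of 75). The median, mean and test differed in sign in 27 of 216 results, of which 0 were called. Correlations of effects are across genes.

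The week number pairs the PBS and cetuximab libraries, since the labels give both cultures the same week. The main fits did not use this pairing, and week as a block was an alternative. Deviations from the arm means correlated within weeks at r of 0.0928 to 0.515, over 0.1 in 9 of 11 weeks, and 7 PBS libraries matched their own week best. The numbers of the clones and parental libraries do not pair samples. Residuals of successive weeks around the line correlated at a median of -0.14 in PBS and -0.132 in cetuximab.

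The 2 alternatives added after the data were seen left out clones 10 and 11 or used the PBS libraries in place of the parental ones. The others were another filter (none, or a floor of 61.5 units), libraries shifted to equal medians, quantile normalisation, a pseudocount of 16, a robust variance model without trend, week as a block, odd weeks alone, other early and late weeks, the baseline library as week 0, leaving out each library of a period or each parental library, batch 2 alone, and for lists an estimated correlation and the fry test. The fit with the baseline as week 0 gave both arms a common start and had no separate arm term. The main fits were tested on simulated data with known changes in the real genes. Of the genes changed 2-fold, 98.5% were recovered over all weeks, 98.5% early, 97% late, 89.6% for late minus early, 79.1% for the slope difference and 49.3% for clones against parental. Of unchanged genes 4 to 22 per comparison were called. The simulated counts were drawn independently, without batch or week effects, and the changed genes were chosen above the filter. For slopes the fold was reached gradually over the weeks. These shares therefore leave out errors from batch or from single parental libraries. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Mitochondrially encoded genes were not used here, and markers of endothelial cells and melanocytes had 1 and 2 tested genes in the time course, below the minimum of 3.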

Results

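RNA was sequenced from SCC25, a human squamous carcinoma line of the tongue that responds to cetuximab, an antibody that blocks the epidermal growth factor receptor (EGFR). One culture received 100 nM cetuximab and a parallel culture received PBS, and each was sampled once a week for 11 weeks. The series also held 3 libraries of untreated parental cells, from batches numbered 0, 1 and 2, and 11 stable cetuximab-resistant clones, numbered 1 to 5 and 7 to 12. Expression was given as upper-quartile normalised gene values for 20531 genes in 36 libraries. Estimated totals, recovered from the value of 1 count in each library, ran from 26100000 to 39300000 counts in PBS and 29500000 to 48800000 in cetuximab. They ran from 20800000 to 35900000 in parental cells and 18400000 to 31900000 in the clones. The weekly libraries of an arm come from 1 culture and stand in for replicates, so p-values measure the spread between weekly samples and not between independent cultures. Folds are on the log2(value + 1) scale, which understates the change of genes with low values.

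The first comparison asked which genes differed between the treated and control cultures over all 11 weeks. Cetuximab-treated cells had higher levels of COL3A1, MUC4 and CLDN1 and lower levels of MAOB, GJB2, GJB6 and KRT14. COL3A1, a fibrillar collagen (Entrez 1281, GRCh37 chromosome 2, 189839099 to 189877472), had 306 ± 79.5 (SD, n = 11) under cetuximab and 33.4 ± 13.4 under PBS, a 9.27-fold difference (log2 3.21 ± 0.19 SE, limma adjusted p = 2.97e-11, higher in 11 of 11 weeks). MAOB, which oxidises amines (Entrez 4129, chromosome X, 43625857 to 43741696), fell from 131 ± 18.2 to 6.52 ± 3.66, a 19.5-fold difference (log2 -4.29 ± 0.22, limma adjusted p = 2.47e-12, lower in 11 of 11 weeks). The mucin MUC4 rose 9.96-fold, the deiodinase DIO2 9.71-fold, the tight junction protein CLDN1 7.76-fold, PPP2R2B 5.78-fold, the protease ADAMTS9 5.03-fold, PDE10A 4.94-fold and MYL9 4.88-fold. The connexins GJB2 and GJB6, which lie beside each other on chromosome 13, fell 6.05-fold and 5.46-fold, PTPRZ1 fell 4.46-fold, ZNF474 4.17-fold, LZTS1 3.99-fold, the immediate early factor EGR3 3.80-fold and ARHGEF6 3.67-fold. Each of these 16 genes went the same way in at least 10 of 11 weeks.

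By group, 14 of 23 measured NF-kB and inflammation genes rose and 0 fell (16 rose when adjusted over the list alone, camera adjusted p = 9.08e-05, adjusted p = 0.644 with an estimated correlation). ICAM1, an adhesion molecule, rose 3.26-fold and SOD2 1.67-fold. Of 21 YAP and TEAD targets, 10 rose, ANKRD1 3.92-fold and IGFBP3 2.95-fold among them, and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00926, adjusted p = 0.644 with an estimated correlation). Of 16 matrix remodelling genes 8 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.0192, adjusted p = 0.644 with an estimated correlation). Of 25 mesenchymal genes 7 rose and 3 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.0446, 0.0514 with week as a block, adjusted p = 0.667 with an estimated correlation). FBN1 and TGFB2 rose 3.74-fold and 3.48-fold, while the collagen cross-linking enzyme LOX fell 1.67-fold. Markers of fibroblasts moved beside these groups: of 5 measured, COL3A1, COL1A1 and LUM rose and 2 did not pass (3 rose adjusted over the list alone, camera adjusted p = 0.0119, adjusted p = 0.644 with an estimated correlation). Interferon genes rose in 10 of 34 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.0119, adjusted p = 0.794 with an estimated correlation), and antigen presentation genes rose in 4 of 17 (1 adjusted over the list alone, camera adjusted p = 0.0192, adjusted p = 0.783 with an estimated correlation).

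Keratinocyte and metabolic lists moved the other way over the 11 weeks. Of 16 basal keratinocyte genes 7 fell, also when adjusted over the list alone (camera adjusted p = 0.000851, adjusted p = 0.644 with an estimated correlation). KRT14 fell 2.19-fold and the integrin ITGA6 1.52-fold. Of 17 keratinocyte differentiation genes 9 fell and 1, KRT80, rose 3.63-fold (10 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00682, adjusted p = 0.644 with an estimated correlation). Of 25 cholesterol synthesis genes 8 fell, also adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.644 with an estimated correlation). Of 30 glycolysis and hypoxia genes 8 fell (6 adjusted over the list alone, camera adjusted p = 0.00682, adjusted p = 0.644 with an estimated correlation), with NDRG1 2.46-fold and the glucose transporter SLC2A1 1.71-fold lower. Of 11 NOTCH pathway genes 5 fell, JAG1 and JAG2 among them, and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.0361, adjusted p = 0.644 with an estimated correlation). The ribosomal protein list went up instead, at a median log2 difference of 0.08. Of its 45 genes 1 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.0446, 0.0848 with week as a block, adjusted p = 0.794 with an estimated correlation).

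Of the growth factor receptors, FGFR1 rose 1.95-fold (log2 0.96 ± 0.13, limma adjusted p = 4.14e-06) and MET 1.27-fold (log2 0.34 ± 0.07, limma adjusted p = 0.000357), each in 11 of 11 weeks. The drug target EGFR fell 1.17-fold, from 18800 ± 1700 to 16000 ± 968 (limma adjusted p = 0.00146, 11 of 11 weeks). ERBB2 and ERBB3 had log2 differences of 0.05 ± 0.04 and -0.05 ± 0.08 that did not pass (limma adjusted p = 0.338 and 0.651). The ERK feedback phosphatase DUSP6 fell 1.54-fold (limma adjusted p = 0.0013, 10 of 11 weeks), and the proliferation marker MKI67 had a log2 difference of -0.10 ± 0.06 (limma adjusted p = 0.174, 0.0261 with week as a block). As a group, 1 of 7 EGFR ligands fell (1 adjusted over the list alone, camera adjusted p = 0.191), 1 of 3 ERBB receptors fell (1 adjusted over the list alone, camera adjusted p = 0.561), and 5 of 19 ERK targets rose while 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.858). In all, limma called 4087 of 12580 tested genes at the adjusted threshold of 0.05, 2196 higher and 1891 lower under cetuximab, of which 225 differed more than 2-fold. Which direction held more calls depended on the scaling, with 1910 higher and 2314 lower after quantile normalisation. With odd weeks alone 1741 genes were called.

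Weeks 1 to 4 stand for the immediate response. Most interferon-stimulated and antigen presentation genes were higher under cetuximab in these weeks, and so were COL3A1 and CXCL10, while the keratins KRT15 and KRT13 were lower. COL3A1 reached 374 ± 72.7 (SD, n = 4) against 35.8 ± 17.3 under PBS, 10.9-fold (log2 3.44 ± 0.26, limma adjusted p = 1.2e-07, 4 of 4 weeks). The cytokine IL32 (Entrez 9235, chromosome 16, 3115298 to 3132193) reached 372 ± 126 against 44.2 ± 17.1, 8.29-fold (log2 3.05 ± 0.41, limma adjusted p = 5.97e-05, 4 of 4 weeks). DIO2 rose 8.30-fold, PCDH19 7.37-fold, MUC4 5.61-fold, PPP2R2B 5.59-fold, DNAH17 5.56-fold and MYL9 5.53-fold. Among the genes that fell, MAOB was 14-fold lower, KRT15 4.00-fold, KRT13 3.68-fold, the thrombin receptor THBD 3.26-fold, GJB2 3.18-fold and PTPRZ1 3.09-fold, all in 4 of 4 weeks. EGR3 fell 4.14-fold and EGR2 3.03-fold (limma adjusted p = 0.0207 and 0.0476), calls that depended on single libraries. The EGR3 call ended without the week 1 or week 4 PBS library (log2 -1.92 and -1.86) or the week 3 cetuximab library (-1.65). The EGR2 call ended without the week 1 or week 4 PBS library (-1.70 and -1.06) or the week 1, 2 or 3 cetuximab library (-1.65, -1.59 and -1.38).

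Of 34 interferon genes 27 rose and 1 fell (30 and 1 adjusted over the list alone, camera adjusted p = 7.41e-14, adjusted p = 0.344 with an estimated correlation). RSAD2, an antiviral enzyme, rose 4.19-fold and USP18 2.39-fold. Of 17 antigen presentation genes 14 rose and 0 fell (15 and 0 adjusted over the list alone, camera adjusted p = 1.23e-11, adjusted p = 0.19 with an estimated correlation), with HLA-B 2.19-fold and HLA-C 1.61-fold higher, paralogs whose reads the counting could share. Of 23 NF-kB and inflammation genes 12 rose and 0 fell (14 and 0 adjusted over the list alone, camera adjusted p = 2.93e-10, adjusted p = 0.219 with an estimated correlation), the chemokines CXCL10 5.20-fold and CCL5 2.92-fold. Mesenchymal genes rose in 11 of 25 and fell in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 6.1e-06, adjusted p = 0.19 with an estimated correlation), with FBN1 4.18-fold, TGFB2 2.55-fold and COL5A1 1.92-fold higher and LOX lower. YAP and TEAD targets rose in 9 of 21 (12 adjusted over the list alone, camera adjusted p = 9.45e-06, adjusted p = 0.22 with an estimated correlation). Matrix remodelling genes rose in 6 of 16 (6 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.000528, adjusted p = 0.119 with an estimated correlation), with ADAM12 3.78-fold and MMP13 2.40-fold higher. The fibroblast markers COL3A1, LUM and COL1A1 rose beside these groups, 10.9-fold, 3.27-fold and 2.14-fold, and DCN did not pass at a log2 difference of 0.22 ± 0.35 (3 of 5 rose, also adjusted over the list alone, camera adjusted p = 0.000164, adjusted p = 0.119 with an estimated correlation).

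Basal keratinocyte genes as a group did not pass early: 3 of 16 fell and 0 rose (5 fell and 4 rose adjusted over the list alone, camera adjusted p = 0.849), at a median log2 difference of 0.14. Keratinocyte differentiation genes fell in 7 of 17 and 1, KRT80, rose (8 and 1 adjusted over the list alone, camera adjusted p = 0.00405, adjusted p = 0.351 with an estimated correlation). The protease KLK7 fell 3.27-fold. Cell cycle genes fell in 7 of 48 (7 adjusted over the list alone, camera adjusted p = 0.000287, adjusted p = 0.709 with an estimated correlation), CENPE 1.47-fold and CCNB2 1.25-fold. Ribosomal protein genes fell in 7 of 45 (16 adjusted over the list alone, camera adjusted p = 1.9e-08, adjusted p = 0.456 with an estimated correlation), at a median log2 difference of -0.15. ERK targets fell in 3 of 19 (3 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.099, 0.0359 with week as a block), DUSP6 1.81-fold. FGFR1 rose 1.99-fold and the epithelial cadherin CDH1 1.39-fold, each in 4 of 4 weeks, while EGFR had a log2 difference of -0.17 ± 0.08 that did not pass (limma adjusted p = 0.167). In all, limma called 2228 genes early, 1279 higher and 949 lower, 232 of them over 2-fold. After quantile normalisation 1182 were higher and 1303 lower. The count was 3874 with week as a block and 1478 without the week 1 cetuximab library.

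**Figure D1:**
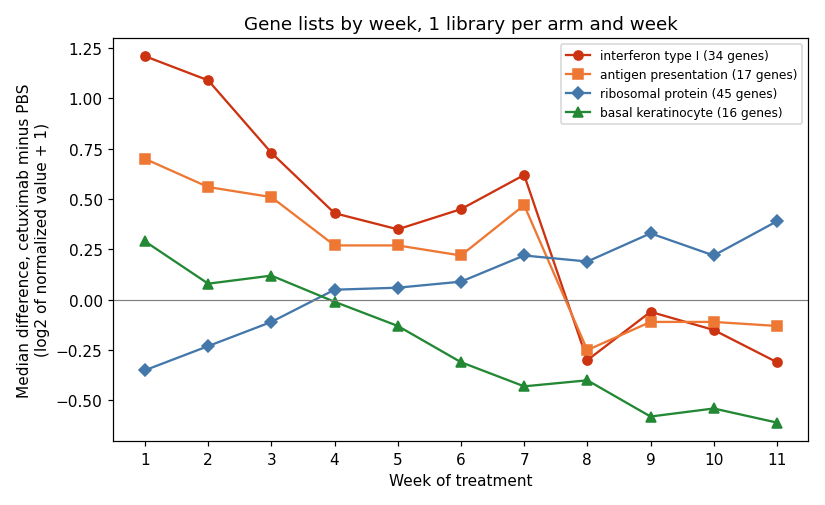
Median difference in log2(normalised value + 1) between the cetuximab and PBS library of each week (y axis) against week of treatment (x axis), 1 line per gene list and 1 library per arm and week. The interferon list runs from 1.21 in week 1 to -0.31 in week 11, the ribosomal protein list from -0.35 to 0.39 and the basal keratinocyte list from 0.29 to -0.61.

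Weeks 8 to 11 stand for the late, acquired part of the course. Here most basal keratinocyte genes and 12 of 30 glycolysis and hypoxia genes were lower under cetuximab, and most ribosomal protein genes were higher. PDE10A, a phosphodiesterase (Entrez 10846, chromosome 6, 165740776 to 166401605), reached 130 ± 9.60 (SD, n = 4) against 7.95 ± 2.49 under PBS, 14.9-fold (log2 3.90 ± 0.22, limma adjusted p = 5.44e-10, 4 of 4 weeks). MAOB fell from 128 ± 10.5 to 3.27 ± 0.822, 30.7-fold (log2 -4.94 ± 0.28, limma adjusted p = 5.44e-10, 4 of 4 weeks). UGT1A10, which shares exons with the other genes of its locus, rose 14-fold, COL3A1 10.4-fold, MUC4 9.91-fold, STOM 9.79-fold, the plasminogen activator PLAT 7.21-fold and the stress cytokine GDF15 6.63-fold. GJB6 fell 12.9-fold, GJB2 11.6-fold, ARHGEF6 9.11-fold, NCKAP5 8.32-fold and LZTS1 6.26-fold. ZNF721 and PIGG, neighbours at the short-arm end of chromosome 4 (419604 to 492945 and 492999 to 533989), fell 13.9-fold and 12.7-fold, and 265 of 438 tested genes of that chromosome were lower.

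Of 45 ribosomal protein genes 40 rose and 0 fell (42 and 0 adjusted over the list alone, camera adjusted p = 2.07e-13, adjusted p = 0.706 with an estimated correlation), RPS13 1.41-fold and RPL7 1.40-fold, both of which have processed pseudogenes that could share reads. Basal keratinocyte genes fell in 12 of 16 (13 adjusted over the list alone, camera adjusted p = 3.1e-07, adjusted p = 0.27 with an estimated correlation). KRT14 fell 3.67-fold, from 89900 ± 4940 to 24800 ± 4280, and KRT5 fell 1.86-fold. The KRT5 difference was 0.00 after quantile normalisation, which fixes the top-ranked gene of every library. Glycolysis and hypoxia genes fell in 12 of 30 (12 adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.706 with an estimated correlation), NDRG1 3.83-fold, the carbonic anhydrase CA12 2.37-fold and SLC2A1 1.78-fold. Cholesterol synthesis genes fell in 7 of 25 (11 adjusted over the list alone, camera adjusted p = 0.0017, adjusted p = 0.706 with an estimated correlation), with STARD4 2.46-fold and MVK 1.32-fold lower. Keratinocyte differentiation genes fell in 9 of 17 and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.706 with an estimated correlation), and ECM1 fell 4.55-fold.

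Interferon genes rose in 0 of 34 and fell in 3 in the late weeks (0 and 1 adjusted over the list alone, camera adjusted p = 0.192), and NF-kB and inflammation genes rose in 6 of 23 (5 adjusted over the list alone, camera adjusted p = 0.084, 0.0369 with week as a block). FGFR1 rose 1.65-fold (limma adjusted p = 0.00307, 4 of 4 weeks). EGFR fell 1.20-fold (limma adjusted p = 0.021, 4 of 4 weeks), a call that ended without the week 8 or week 9 PBS library (log2 -0.22 in both) or the week 10 cetuximab library (-0.24). DUSP6 had a log2 difference of -0.38 ± 0.19 (limma adjusted p = 0.132, 0.015 with week as a block) and HBEGF of -1.03 ± 0.51 (limma adjusted p = 0.135, 0.000633 with week as a block). The fibroblast markers COL3A1 and LUM rose and PDPN fell, with log2 differences of 3.38 ± 0.26, 2.37 ± 0.35 and -0.47 ± 0.09 (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.192). In all, limma called 3990 genes late, 1907 higher and 2083 lower, 438 of them over 2-fold. With median-centred libraries 2088 were higher and 1933 lower.

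**Figure D2:**
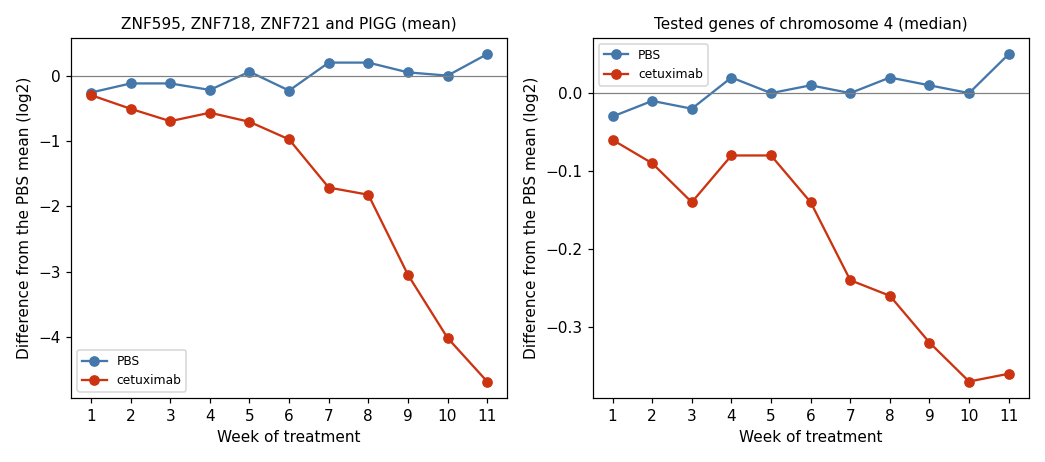
Difference from the PBS mean in log2(normalised value + 1) (y axes) against week of treatment (x axes) for the mean of 4 genes at the short-arm end of chromosome 4, left, and the median of the tested genes of chromosome 4, right, 1 library per arm and week. Under cetuximab the 4 genes go from -0.29 in week 1 to -4.69 in week 11 and the chromosome median from -0.06 to -0.36.

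The difference between the late and early effects was tested directly. The transcription factor ETV1 (Entrez 2115, chromosome 7, 13930854 to 14031050) went from a log2 difference of -1.13 ± 0.47 early, which did not pass, to 2.72 ± 0.47 late, a change of 3.85 ± 0.66 (limma adjusted p = 0.000682). STOM gained 3.67 ± 0.35, PDE10A 3.34 ± 0.31, PAX7 3.23 ± 0.42 and GLB1L2 3.23 ± 0.31, and ADAM28 changed by -4.09 ± 0.47, PIGG by -3.43 ± 0.48, ZNF721 by -3.43 ± 0.60, ZNF718 by -3.13 ± 0.57 and ZNF595 by -2.84 ± 0.57. In this test 24 of 34 interferon genes were lower late than early and 0 higher (28 and 0 adjusted over the list alone, camera adjusted p = 1.93e-11, adjusted p = 0.542 with an estimated correlation), as were 14 of 17 antigen presentation genes (14 adjusted over the list alone, camera adjusted p = 4.1e-09, adjusted p = 0.38 with an estimated correlation), 11 of 16 basal keratinocyte genes (12 adjusted over the list alone, camera adjusted p = 3.95e-07, adjusted p = 0.3 with an estimated correlation) and 5 of 23 NF-kB genes (5 adjusted over the list alone, camera adjusted p = 0.0186, adjusted p = 0.689 with an estimated correlation). Of 25 mesenchymal genes 9 were lower and 2 higher (14 and 2 adjusted over the list alone, camera adjusted p = 0.000334, adjusted p = 0.432 with an estimated correlation). Higher late than early were 40 of 45 ribosomal protein genes (43 adjusted over the list alone, camera adjusted p = 5.04e-24, adjusted p = 0.3 with an estimated correlation), 6 of 19 ERK targets (6 adjusted over the list alone, camera adjusted p = 0.00806, adjusted p = 0.623 with an estimated correlation), and 5 of 48 cell cycle genes (1 adjusted over the list alone, camera adjusted p = 0.00536, adjusted p = 0.694 with an estimated correlation). Of 25 epithelial genes 7 were higher and 2 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.0377, adjusted p = 0.689 with an estimated correlation). In all, limma called 2461 genes, 1083 higher and 1378 lower late than early, and 4179 with week as a block. With median-centred libraries 1302 were higher and 1254 lower, and after quantile normalisation 1331 and 1235.

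**Figure D3:**
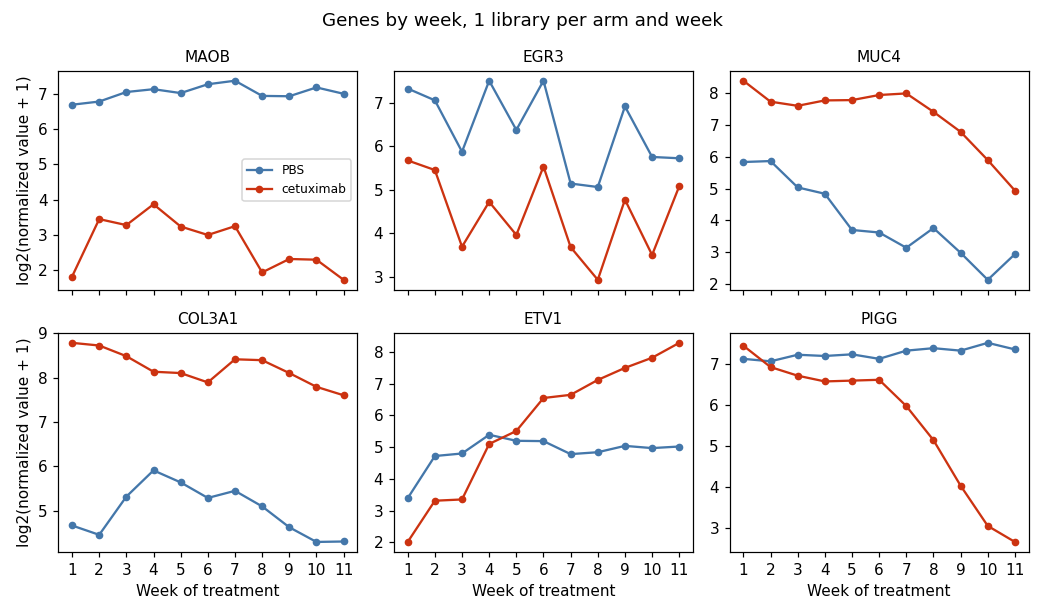
log2(normalised value + 1) (y axes) against week of treatment (x axes) for 6 genes in the PBS and cetuximab cultures, 1 library per arm and week. ETV1 under cetuximab goes from 2.01 in week 1 to 8.29 in week 11 and PIGG from 7.45 to 2.67, while MAOB lies between 1.73 and 3.87 under cetuximab and between 6.69 and 7.37 under PBS.

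Change per week was also fitted as a straight line in each arm. Under cetuximab ETV1 rose by 0.61 ± 0.04 log2 per week, SLC43A1 by 0.39 ± 0.04, GLB1L2 by 0.39 ± 0.03, UGT1A10 by 0.34 ± 0.04 and ACOXL by 0.29 ± 0.03, while ADAM28 changed by -0.52 ± 0.04, PIGG by -0.46 ± 0.04, ZNF721 by -0.45 ± 0.05, ZNF718 by -0.41 ± 0.04 and TRAF1 by -0.38 ± 0.04. All 45 ribosomal protein genes rose with week (45 adjusted over the list alone, camera adjusted p = 1.03e-25, adjusted p = 0.136 with an estimated correlation), and 21 of 23 NF-kB genes fell (22 adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.328 with an estimated correlation). Under PBS the line moved too: DOCK10 rose by 0.28 ± 0.04 log2 per week and EYA2, ELF3, MUC4 and PELI2 changed by -0.43 ± 0.04, -0.35 ± 0.05, -0.35 ± 0.05 and -0.33 ± 0.04. Of 25 cholesterol synthesis genes 5 rose with passage in PBS (13 adjusted over the list alone, camera adjusted p = 4.06e-07, adjusted p = 0.368 with an estimated correlation). NF-kB genes also fell with week in PBS, 3 of 23 (5 adjusted over the list alone, camera adjusted p = 1.21e-05, adjusted p = 0.368 with an estimated correlation). Basal keratinocyte genes rose there, 6 of 16 (9 adjusted over the list alone, camera adjusted p = 1.21e-05, adjusted p = 0.0801 with an estimated correlation). The slopes differed between arms for 3440 genes in limma, 1536 more positive and 1904 more negative under cetuximab. In that test 12 of 16 basal keratinocyte genes were more negative (12 adjusted over the list alone, camera adjusted p = 2.74e-07, adjusted p = 0.0236 with an estimated correlation), the 1 list call of 75 that held with an estimated correlation. Within the arms limma called 5789 slopes under cetuximab, 2542 up and 3247 down, and 1010 under PBS, 327 up and 683 down. After quantile normalisation 3158 slopes under cetuximab were up and 2759 down, and the slope difference was more positive for 1828 genes and more negative for 1695. With median-centred libraries the slope difference was more positive for 1797 and more negative for 1700. With odd weeks alone the PBS count was 97 and the slope difference count 1967, and with the untreated baseline library as week 0 the PBS count was 2986. That setting gave 3963 genes for the slope difference, but of the 3438 calls tested in both only 1625 were called in the same direction. Its fit gave both arms a common start and had no separate arm term, unlike the main fit. A steady difference between the arms therefore enters its slopes, so these counts do not show the effect of the added library alone.

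The early and late effects were compared across genes, which are not independent replicates. Over 12580 genes they correlated with Pearson's r = 0.365 and Spearman's rho = 0.226 (covariance 0.0492), and the effects share no library. COL3A1, MAOB, MUC4 and GJB2 were among the genes called in the same direction in both. Both calls were higher for 395 genes against 194 in independent lists and lower for 371 against 157, and 178 genes were called in opposite directions against 356.

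The clones were compared with the parental line to ask what distinguishes stable resistant cells. Part of the interferon and NF-kB genes and immediate early genes such as FOSB and EGR1 were lower in the clones, and AKAP12 and NRCAM were higher. The labels give no treatment for the clones, and their source names mention PBS, so whether drug was present when they were sampled is not certain. FOSB, a subunit of the AP-1 factor (Entrez 2354, chromosome 19, 45971253 to 45978437), had 351 ± 310 (SD, n = 11) in the clones and 12400 ± 2120 (n = 3) in parental cells, 45.6-fold lower (log2 -5.51 ± 0.57, limma adjusted p = 0.000263, lower in 11 of 11 clones). The nuclear receptor NR4A1 (Entrez 3164, chromosome 12, 52416616 to 52453291) had 103 ± 43.5 against 3620 ± 3320, 26.8-fold lower (log2 -4.74 ± 0.49, limma adjusted p = 0.000263, 11 of 11 clones). FOS was 58-fold lower, LY6D 42-fold, GJB6 37-fold, the epidermal factor ZNF750 28-fold, SERPINB3 25.6-fold and EGR2 25.3-fold. AKAP12, a kinase anchor (Entrez 9590, chromosome 6, 151561102 to 151679694), had 2470 ± 1660 in the clones and 348 ± 199 in parental cells, 6.84-fold higher (log2 2.77 ± 0.58, limma adjusted p = 0.0186, 11 of 11 clones). SULT1B1 was 14.7-fold higher, the adhesion molecule NRCAM 9.94-fold, KCNA7 9.37-fold, ADAMTS16 7.15-fold, IFNE 6.08-fold, AGPAT9 5.88-fold and ZNF767 5.6-fold. Several of these calls rested on single parental libraries. Without parental library 0 the calls ended for FOS (log2 -5.36), LY6D (-4.59), GJB6 (-4.63), SERPINB3 (-4.00), AKAP12 (2.13), SULT1B1 (4.13), NRCAM (2.40), KCNA7 (2.37), ADAMTS16 (2.66), IFNE (2.45), AGPAT9 (2.24) and ZNF767 (2.55). Without library 1 they ended for LY6D (-5.36), GJB6 (-4.44), SERPINB3 (-3.80), AKAP12 (3.13), SULT1B1 (3.85), NRCAM (4.08), KCNA7 (3.19), ADAMTS16 (2.29) and IFNE (1.84), and without library 2 for SULT1B1 (3.66). ZNF750 and EGR2 fell below the filter without library 0 or 1, and EGR2 also without library 2. Against the parental library of the clones' own batch the differences of several genes were smaller: log2 -1.57 for SERPINB3 and -2.51 for GJB6, each with 2 of 11 clones above that library, and -1.93 for ZNF750, -2.52 for EGR2 and -3.21 for NR4A1. They were 1.45 for KCNA7, 1.11 for ZNF767, 1.39 for ADAMTS16, with 10 of 11 clones above that library, and 0.77 for IFNE, with 9 of 11 above.

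Interferon genes fell in 16 of 34 and rose in 0 (25 and 0 adjusted over the list alone, camera adjusted p = 4.78e-19, adjusted p = 0.295 with an estimated correlation), with IRF7 5.41-fold and PARP9 4.50-fold lower. Antigen presentation genes fell in 8 of 16 (11 adjusted over the list alone, camera adjusted p = 1.65e-10, adjusted p = 0.229 with an estimated correlation), with the immunoproteasome subunit PSMB8 2.49-fold lower. NF-kB and inflammation genes fell in 7 of 22 (11 adjusted over the list alone, camera adjusted p = 3.96e-10, adjusted p = 0.295 with an estimated correlation), with CXCL2 15.5-fold and NFKBIA 4.23-fold lower. ERK targets fell in 5 of 19 (5 adjusted over the list alone, camera adjusted p = 0.001, adjusted p = 0.431 with an estimated correlation), EGR1 14.5-fold and DUSP5 5.30-fold. Among stress genes 2 of 24 fell, ATF3 15.9-fold and PPP1R15A 3.80-fold (3 adjusted over the list alone, camera adjusted p = 0.000905, adjusted p = 0.431 with an estimated correlation). Glycolysis and hypoxia genes fell in 4 of 29 and 1 rose (9 and 1 adjusted over the list alone, camera adjusted p = 4.6e-05, adjusted p = 0.137 with an estimated correlation), and NOTCH pathway genes fell in 2 of 11, HES1 5.06-fold (4 adjusted over the list alone, camera adjusted p = 0.00578, adjusted p = 0.431 with an estimated correlation). Epithelial genes fell in 2 of 25, GRHL1 5.86-fold and OVOL1 15-fold (2 adjusted over the list alone, camera adjusted p = 6.02e-05, adjusted p = 0.538 with an estimated correlation). Differentiation genes passed in 0 of 16 (5 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00257, adjusted p = 0.431 with an estimated correlation). Cell cycle genes rose in 5 of 48 (9 adjusted over the list alone, camera adjusted p = 1.39e-06, adjusted p = 0.431 with an estimated correlation), with MCM10 2.19-fold and MCM7 1.96-fold higher, and ribosomal protein genes rose in 1 of 45, RPL5 (1 adjusted over the list alone, camera adjusted p = 9.18e-05, adjusted p = 0.553 with an estimated correlation). Without parental library 0 the calls ended for IRF7 (log2 -2.51), PARP9 (-1.91), DUSP5 (-2.41), GRHL1 (-1.86), OVOL1 (-3.47), MCM10 (0.82), MCM7 (0.62) and RPL5 (0.74). Without library 1 they ended for IRF7 (-2.07), PARP9 (-1.99), DUSP5 (-2.04), GRHL1 (-2.30), OVOL1 (-3.61), MCM10 (1.08), MCM7 (1.04) and RPL5 (0.74). Against the parental library of the clones' own batch the log2 differences were -1.86 for IRF7, -1.29 for PARP9, -1.69 for DUSP5, -1.36 for HES1, -0.68 for GRHL1, -2.46 for OVOL1, 0.40 for MCM10, 0.42 for MCM7 and 0.59 for RPL5. For PARP9 and GRHL1 1 of 11 clones lay above that library.

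The counts within lists also rested on these libraries. Without parental library 0 or library 1, 0 interferon, 0 cell cycle, 0 glycolysis and hypoxia, 0 epithelial and 0 ribosomal protein genes passed in limma, and 1 antigen presentation gene, 2 NF-kB genes and 1 NOTCH pathway gene passed. At an unadjusted p under 0.05 there were 22, 5, 9, 2 and 4 genes of the first 5 of these lists without library 0 and 24, 15, 9, 3 and 3 without library 1. Of the ERK targets 1 passed without library 0 and 2 without library 1. The median log2 difference of the interferon list was -1.93 with all 3 libraries, -1.83 without library 0 and -1.86 without library 1, and that of the NF-kB list was -2.12, -2.42 and -1.59. For the cell cycle list it was 0.39, 0.10 and 0.48, for the ribosomal protein list 0.28, 0.23 and 0.14, for the ERK targets -0.46, -0.70 and -0.22, and for the NOTCH pathway -0.56, -0.30 and -0.40. Within batch 2, 0 genes of these 6 lists passed in limma, with 7 interferon, 3 NF-kB, 0 cell cycle, 0 ribosomal protein, 5 ERK target and 1 NOTCH pathway genes at an unadjusted p under 0.05. The medians there were -1.48, -1.14, 0.04, -0.17, -0.32 and -0.56, so the ribosomal protein list changed sign and the cell cycle list lay near 0. With all 3 libraries and within batch 2 the medians were -0.86 and -0.74 for antigen presentation, -0.41 and -0.50 for stress, -0.46 and -0.27 for glycolysis and hypoxia, -1.0 and -0.79 for epithelial and -1.36 and -0.75 for differentiation genes. Without library 2 more genes passed in some lists, with 15 cell cycle genes (median 0.54) and 14 ribosomal protein genes (median 0.58) higher and 5 stress, 7 glycolysis and hypoxia, 4 NOTCH pathway and 5 differentiation genes lower, and 1 differentiation gene higher.

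The EGFR ligand HBEGF was 19.7-fold lower in the clones (limma adjusted p = 0.00866, 11 of 11 clones), a call that ended without parental library 0 (log2 -4.22) or library 1 (-3.65) and a difference that was -2.86 within batch 2, whereas EGFR, FGFR1, AXL and MET had log2 differences of -0.73 ± 0.36, 1.56 ± 0.77, 1.43 ± 0.56 and 0.83 ± 0.30 that did not pass (limma adjusted p = 0.235, 0.234, 0.144 and 0.108). VIM and CDH1 had larger standard errors, with log2 differences of 1.87 ± 1.41 and -0.91 ± 1.62 (limma adjusted p = 0.445 and 0.77). In all, limma called 611 of 12566 genes, 343 higher and 268 lower in the clones, 376 of them over 2-fold. The count rested on single parental libraries. It was 21 without parental library 0 (3 higher, 18 lower), 35 without library 1 (6 and 29) and 2384 without library 2 (1427 and 957). With no filter 295 genes were higher and 337 lower, so which direction held more calls depended on the setting. FOSB, NR4A1, EGR1, ATF3, NFKBIA, CXCL2, HES1, PPP1R15A and PSMB8 passed without each parental library in turn. Within batch 2, where 11 clones face 1 parental library, 1 gene passed, ZFP36 (log2 -2.87, limma adjusted p = 0.00679), named here after its value was seen. The spread there comes from the clones alone, and the lone parental library is assumed to vary like them. FOSB, NR4A1, EGR1 and NFKBIA had log2 differences of -5.23, -3.21, -3.88 and -1.81 that did not pass. Clones 10 and 11 correlated least with the other clones, and without them 1259 genes were called, an alternative chosen after the data were seen.

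**Figure D4:**
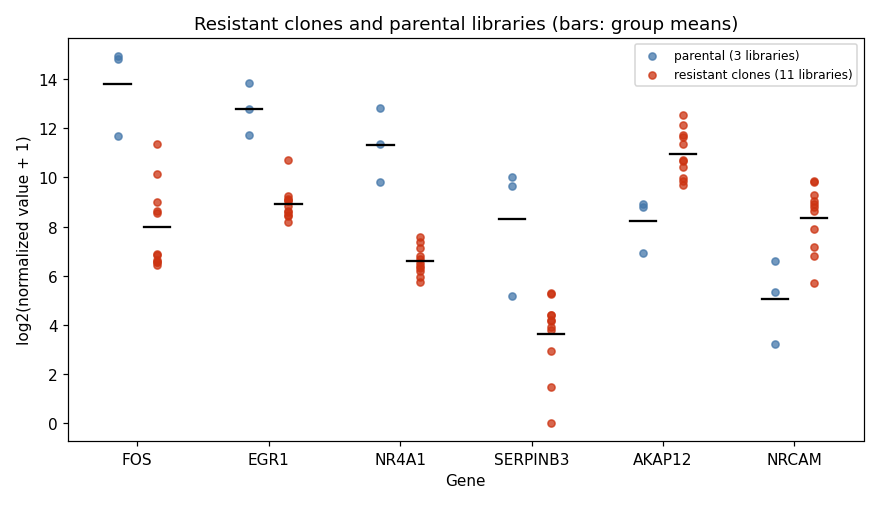
log2(normalised value + 1) (y axis) of 6 genes (x axis) in the 3 parental libraries and the 11 resistant clones, 1 point per library, with bars at the group means. For EGR1 the clones lie between 8.20 and 10.70 and the parental libraries between 11.72 and 13.84, and for AKAP12 the clones lie between 9.70 and 12.53 and the parental libraries between 6.91 and 8.92.

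The late effect in the treated culture was set against the clone effect across genes, which share no library. Over 12375 genes Pearson's r was 0.257 and Spearman's rho 0.29 (covariance 0.0697), and r was 0.169 within batch 2. GJB6 and NDRG1 were lower in both and RPL5 higher in both. The clone calls of these 3 genes ended without parental library 0 (log2 -4.63, -1.25 and 0.74) or library 1 (-4.44, -1.68 and 0.74), and within batch 2 their differences were -2.51, -0.88 and 0.59. Both calls were higher for 84 genes against 48.7 in independent lists and lower for 80 against 44.2, and 15 genes were called in opposite directions against 93.8. These overlaps rested on single parental libraries: without library 0 both calls were higher for 0 genes and lower for 5, without library 1 for 0 and 10, and without library 2 for 283 and 245. Opposite calls numbered 0, 1 and 89 in these settings.

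The spread between clones was set against that of weekly samples of 1 control culture, which were not separately derived. The median correlation between libraries was 0.933 for the clones, 0.991 for PBS and 0.905 for the 3 parental libraries, which were less alike than the clones. The parental libraries come from 3 batches and the clones from 1, so this difference cannot be told apart from batch. The SD over clones had a median of 0.364 log2 across genes, against 0.118 for the PBS libraries around a straight line over weeks, a median ratio of 3.18. The ratio was above 2 for 10100 of 12547 genes (80.5%).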

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

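Of the tests in this part, those of ERK output and of genes in the first 10 Mb of chromosome 4 were chosen only after the result was seen, and so were the regroupings within batch 2 and the list of immediate early genes. Errors after ± in this part come from resampling genes, which are not independent, and hold no spread between libraries.

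Regroupings of the samples were used to ask whether chance could give as many genes. For cetuximab against PBS over all weeks, 1 of 100 regroupings, the real one, reached 4087 genes, and the highest other gave 593. With the arms exchanged within weeks it was again 1 of 100, with 2289 as the highest other. In weeks 1 to 4, 1 of 35 splits reached 2228 genes. The highest other gave 1331 and set PBS weeks 1, 3 and 4 with cetuximab week 4. Among the 8 splits that part all 4 week pairs the highest other gave 0. In weeks 8 to 11, 1 of 35 splits reached 3990, the highest other gave 2, and among the splits that part 4 pairs it gave 0. For clones against parental cells 1 of 100 reached 611, and the highest other gave 317, with clone 12 in place of parental library 2. The real grouping alone reached these weekly counts, a share under 0.05, which argues against chance within the cultures sampled. The 8 splits that part all 4 pairs are too few by themselves for such a share. With 1 culture per arm, no regrouping can tell an effect of cetuximab from another difference between the cultures. The clone regroupings ignore batch, which is confounded with group for parental libraries 0 and 1. Within batch 2 there are 12 regroupings, too few for a share under 0.05. There the real one called 1 gene in limma and the highest other, clone 10 alone, called 1345.

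The early and late effects of cetuximab differed in a direct test for 2461 genes. Of the regroupings of arms within the early and late weeks, 2 of 100 gave as many. The highest other gave 3922, with the arms of every late library exchanged, which adds the early and late effects in place of subtracting them. The slope per week differed between arms for 3440 genes, reached by 1 of 100 exchanges of the arms within weeks, with 3175 as the highest other. Genes with the largest differences between late and early effects were ETV1 (log2 3.85), STOM (3.67), PDE10A (3.34), PAX7 (3.23) and GLB1L2 (3.23) upward. Downward they were ADAM28 (-4.09), PIGG (-3.43), ZNF721 (-3.43), ZNF718 (-3.13) and ZNF595 (-2.84).

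Neighbouring genes at the short-arm end of chromosome 4, ZNF595, ZNF718, ZNF721 and PIGG, fell late under cetuximab by log2 -3.25, -3.49, -3.79 and -3.67. Reads shared between zinc finger paralogs could not be judged inside this stretch, since PIGG alone (-3.67) lies outside that family. The 69 genes of the first 10 Mb outside the family, PIGG included, had a median of -0.48 ± 0.03 (54 lower, 1 higher). Much of chromosome 4 was lower late (265 of 438 genes, median -0.34), so that median cannot decide on shared reads either. Of genes with a mean under 1 in PBS and parental libraries, 0 had a mean over 250 late under cetuximab. This argues only against many cells of a line that expresses such genes. A related line or a small share of other cells need not give any, so these are not excluded. Loss of a chromosome segment in the treated culture is a candidate explanation, although copy number was not measured. Under cetuximab the mean of the 4 genes went from -0.29 in week 1 to -4.69 in week 11 against the PBS mean. Loss in a small share of the cells would not give the week 11 value. Late, 18 windows of 10 Mb had 60% or more of their genes called in 1 direction, against at most 2 in 1000 shuffles of gene positions. Of them 13 were on chromosome 4 and lay along it, with medians of -0.65 to -0.32. They show a wider and milder shift and do not account for the 4 end genes, past which ATP5I fell by only -0.43. Outgrowth of cells like clone 1, whose 4 genes lay -6.30 from the parental mean, stays open. Clone 1 had rank 1 of 11 in correlation with the late change outside chromosome 4 (r = 0.241). This rank met the condition set beforehand for outgrowth. Clone 1 had only rank 3 with the late minus early change (0.11), behind clone 8 (0.33), a comparison that was not part of that condition.

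Immediate early genes were lower in the clones than in parental cells, 13 of 17 tested, with a median log2 difference of -3.84. The count was 5 of 16 without parental library 0 (median -2.92), 10 of 16 without library 1 (-3.04) and 13 of 16 without library 2 (-3.15). Clones 10 and 11, which stood apart, are argued against as the source, since the median without them was -3.72. Batch stays open: against the parental library of the clones' batch the median was -2.52, with all 11 clones between -3.25 and -2.12, a value that met the bound set beforehand against batch, but that bound was wrong to rely on 1 parental library, which excludes nothing. Handling of the parental cultures before lysis also stays open. PBS cultures lay 2.23 ± 0.50 above the clones, which met the bound of 2 set beforehand against handling. The value lies within its error of that bound, and the error holds only the spread over genes. Cetuximab cultures lay 2 ± 0.5 above the clones, and both cultures come from another batch than the clones. Lower ERK output could not be judged. The median of 9 ERK feedback genes was -0.09, which met the bound written against lower ERK output after the result was seen. The genes ranged from -2.33 to 1.40, too wide a spread to rely on that bound. Resistance itself, the difference the design names, may contribute.

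Ribosomal protein genes were higher late than early under cetuximab, with a median change of log2 0.43 (early -0.15, late 0.28). For transcript length, 3425 other genes of 446 to 1214 bases, the range of most ribosomal protein genes, had a median of 0.01 ± 0.005. For scaling or a few abundant genes, 2128 other genes at mean log2 levels of 10.75 to 14.42 had a median of -0.02 ± 0.006. Genes were not matched singly, and the median of all tested genes was -0.01. The values argue only against a shift shared by genes across those ranges. The change was 0.46 with median-centred libraries and with quantile normalisation, which argues against the scaling. Reads shared with pseudogenes were not tested, and no biological explanation was tested, so the source stays open.

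Single libraries far from the other 3 of their group were found in 8 of 218 groups (3.67%), near the 1 in 20 that chance gives. The gap to the nearest value over the whole range, both on the log2 scale, was 0.904 for ERBB3 in cetuximab week 4 (817 against 577 to 597), 0.89 for HLA-B in cetuximab week 1 (20300 against 13600 to 14300) and 0.843 for HBEGF in PBS week 3 (322 against 824 to 982). In the late weeks it was 0.915 for VIM in cetuximab week 10 (6860 against 5690 to 5780) and 0.834 for AREG in cetuximab week 11 (115 against 170 to 184). From PBS week 10 came ITGA6 with 0.889 (16800 against 14400 to 14700), GDF15 with 0.869 (44.3 against 89.2 to 99.1) and STARD4 with 0.858 (195 against 294 to 315).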

How the results depend on the processing

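The alternatives without clones 10 and 11 and with PBS libraries in place of parental ones were chosen after the data were seen. Of 3493 values of named genes under alternatives, 3264 kept their side of the threshold, 173 lost the call, 55 gained one and 1 reversed. Of 594 list values 465 kept their side, 93 lost the call, 36 gained one and 0 reversed. A reversal was counted only for a result called in either setting, so changes of sign among uncalled results were not counted. With an estimated correlation 74 of 75 list calls were lost.

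With odd weeks alone, which use fewer libraries, 1741 genes were called over all weeks, 1967 for the slope difference and 97 for the PBS slope. With week as a block 5379 were called over all weeks, 3874 early, 5581 late, 4179 for late minus early and 5051 for the slope difference. With the untreated baseline as week 0 the PBS slope gave 2986, and 1625 of 3438 slope difference calls were called in the same direction. That fit also gave both arms a common start, so the added library and the changed model cannot be told apart. The cause was not tested. Leaving out 1 library gave 1478 (without cetuximab week 1) to 3158 genes early, 3312 to 3855 late and 1842 to 3216 for late minus early.

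Clones against parental cells gave 21 to 2384 genes without 1 parental library (21, 35 and 2384 without libraries 0, 1 and 2). Within batch 2, with 1 parental library, 1 gene passed in limma, and 471 had an unadjusted p under 0.05. Without clones 10 and 11 the count was 1259, with 609 of the 610 main calls tested there called in the same direction. With PBS libraries in place of parental ones it was 6585, and MCM4 reversed to log2 -0.01. The cause was not tested, and here batch and group differ together. Correlations across genes and the clone spread moved by less than their jackknife errors under other filters and quantile normalisation. So did the correlation of late and clone effects within batch 2 and without clones 10 and 11. Its jackknife error of 0.111 takes in leaving out each parental library, but its values without single libraries are not given. The clone comparison recovered 49.3% of 2-fold changes simulated without batch effects, and low values limit precision for genes near the filter.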

Other observations

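Gene positions were tabulated by chromosome outside the named comparisons, after the data were seen. In the clones 33 of 107 tested genes of chromosome 21 were lower than in parental cells and 2 were higher, with a median log2 difference of -0.50, and the chromosome median lay between -0.73 and -0.21 in all 11 clones. On chromosome 7, 49 of 586 genes were higher and 1 lower (median 0.21), and on chromosome 19, 62 of 862 were higher and 13 lower (median 0.35). These calls rested on single parental libraries: without library 0 there were 1 lower on chromosome 21, 1 higher on chromosome 7 and 0 higher on chromosome 19. Without library 1 there were 5, 1 and 0, and without library 2 there were 37, 101 and 256, with 12 genes of chromosome 21 higher. The median of chromosome 21 was -0.55, -0.47 and -0.38 without libraries 0, 1 and 2 and -0.49 within batch 2. In the same settings it was 0.28, 0.15, 0.23 and 0.18 for chromosome 7 and 0.28, 0.28, 0.53 and 0.02 for chromosome 19. Late under cetuximab the median was -0.20 on chromosome 21, with 45 of 111 genes lower, and also -0.20 on chromosome 14, with 196 of 428 lower. In the clones chromosome 14 had a median of -0.07.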
